A study of Homo sapiens with 12 samples.

How the data were processed

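Gene expression was measured on an Affymetrix expression array in 12 samples of the human lung adenocarcinoma line A549, sorted by Hoechst dye exclusion into side population (SP) and non-SP cells, with or without an EpCAM antibody, 3 biological replicates in each of 4 groups. The deposited values are RMA log2 expression values per probe set, per the submitters' processing notes, which give no version of RMA and do not say which arrays were processed together. The values ranged from 2.43 to 14.95 with 0 negative values, and no further normalization was applied for the main results.

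The sorted values of the SP and non-SP array of the same treatment and replicate number differed by a mean of 0.00933 to 0.0215, against 0.0458 to 0.525 for all other array pairs. The arrays thus look normalised in these 6 pairs and not together, which the processing notes do not state. Fraction contrasts lie within such a set, while antibody contrasts cross sets. Array medians lay between 5.58 and 6.24.

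Gene names came from a probe table. The 62 control probe sets were left out of tests. Of the other 54613, 41091 had exactly 1 gene symbol, 1801 had several and 11721 had no entry in the probe table; probe sets without a single gene name were not named. Symbols were matched to current ones by gene identifier. Probe sets were kept when their mean over the 12 arrays was above the 40th percentile (5.39), and each gene was represented by its kept probe set with the highest mean. This left 14649 genes of 19775 with a probe set. Genome positions are not given, since the values are tied to probe sets and not to a genome build.

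Differential expression was tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with a mean for each group over the 12 arrays, moderated two-sided tests without trend, and Benjamini-Hochberg adjustment over all genes tested within a contrast. A gene passed at an adjusted p under 0.05. The 7 contrasts were SP against non-SP in untreated cells, in treated cells and averaged, antibody against untreated in non-SP, in SP and averaged, and the interaction. Before calls were compared, pairing was checked from correlations of deviations from group means. The SP and non-SP arrays of the same treatment and number correlated with r of 0.62 to 0.89 (0.61 to 0.89 after quantile normalization), whereas treated and untreated arrays of number 2 had r of -0.11 in non-SP and -0.18 in SP cells. For numbers 1 and 3 the treated and untreated arrays had r of 0.73 and 0.60 in non-SP and 0.71 and 0.64 in SP cells. The 6 sorted pairs were therefore used for a limma fit of within-pair differences, added after these correlations were seen, and its values stand beside those of the planned fit. The labels do not say that the arrays of a pair come from the same sort, and the pairing rests on these correlations. Since the arrays of a pair also look normalised together, the correlations cannot tell a shared sort from shared processing. The 6 pairs were taken as independent of each other, which was not tested. Estimates are identical in both fits, and the SE and p differ.

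Gene lists numbered 38 and were fixed before the data were examined, as were the contrasts, the filter, the other settings first listed and the rule for named genes. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. Members were counted over all genes tested and adjusted over the list alone. List means per pair were tested with an exact two-sided sign-flip test, which cannot go below 0.03125 with 6 pairs; 3 samples against 3 cannot go below 0.1. Correlations of effects across genes are descriptive.

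The rule for named genes took, per contrast, the 10 largest rises and 10 largest falls among passing genes whose replicates did not overlap, up to 4 genes of smallest p from each list that passed or held passing members, 14 genes fixed in advance (EPCAM, ABCG2, ABCB1, ABCC1, CD44, PROM1, ALDH1A1, SOX2, POU5F1, NANOG, MYC, CCND1, MKI67 and CDKN1A, of which 10 were tested), and, where fewer than 5 passed, the 5 of smallest p of each sign. Over sorted pairs the condition on replicates was the same sign in every pair, a change made with the added fit, since overlap between groups ignores pairing.

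The fits were tested on simulated data of the same size and pair structure, with 100 changed genes of each size of change. Noise was drawn independently for each gene, so the false calls leave out the correlation between genes in the real arrays. The paired fit called 84% of changes of 0.5 and 99% of changes of 1 on the log2 scale with 9 false calls, and the unpaired fraction contrast called 18% and 65% with 0 false calls. For the averaged antibody contrast the planned fit treats both arrays of a pair as independent. In the simulation it called 81% of changes of 1, with 302 false calls, while a fit of pair means called 36%, with 6 false calls. Alternatives covered the block on replicate number, random blocks, quantile normalization, median centring, the filter, the choice of probe set, trend and robust moderation, array weights, a fold minimum of 1.5, an adjusted p under 0.01, ratios of control probe sets as covariates, and leaving out each array or pair. Other groupings of the samples were counted for the gene counts, the list counts by camera and the correlations of effects. Figures were drawn with matplotlib 3.10.9.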

Results

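A549 is a human lung adenocarcinoma cell line. Its cells were incubated with the DNA-binding dye Hoechst at 5 µg/ml for 90 min and sorted into the side population (SP), which pumps the dye out and stays weakly stained, and the remaining cells (non-SP). Cultures were either untreated or exposed to a monoclonal EpCAM antibody at 100 µg/ml for 48 h. The labels call this antibody anti-mouse EpCAM and do not say whether mouse is the host or the target species. RNA from each sort was hybridised to an Affymetrix expression array with 54613 probe sets besides controls. The 4 groups (untreated non-SP, untreated SP, antibody-treated non-SP and antibody-treated SP) held 3 biological replicates each, 12 arrays in all. The number of arrays limits the precision of every value. Values are RMA log2 values and ranged from 2.43 to 14.95. After a filter on dim probe sets, 14649 genes were compared.

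The SP and non-SP arrays of the same treatment and replicate number resembled each other more than SP and non-SP arrays of different numbers did. Their deviations from the group means correlated across genes with r of 0.62 to 0.89 in the 6 pairs. Fraction contrasts are therefore given over these 6 sorted pairs, a treatment of the data added after those correlations were seen, beside the planned test that takes the 12 arrays as independent. The labels do not say that the arrays of a pair come from the same sort, and every call over pairs depends on that reading. The arrays of a pair also look normalised together, so the correlations cannot tell a shared sort from shared processing. The same replicate numbers in treated and untreated cells gave r of 0.73, -0.11 and 0.60 in non-SP arrays, so they were not taken as pairs. For numbers 1 and 3 this exceeded the highest r of the untreated array with treated arrays of other numbers (-0.37 and 0.40). Treated and untreated pairs of these numbers may thus not be independent. Every SE and p over 6 pairs takes the pairs as independent, which was not tested.

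The first question was how SP cells differ from non-SP cells, over both treatments. ABCG2, the efflux pump that exports Hoechst dye, rose in SP cells by 0.49 ± 0.06 on the log2 scale (SE, n = 6 pairs), which is 1.40-fold, with adjusted p = 0.00375 and a higher value in all 6 pairs. EPCAM, the cell adhesion molecule the antibody is named for, rose by 0.26 ± 0.06 (adjusted p = 0.0435), also in all 6 pairs. The largest rises in SP cells included the nuclear receptor NR4A3 at 0.70 ± 0.08, the small GTPase RND1 at 0.65 ± 0.07, the chemokine CXCL2 at 0.63 ± 0.06, the vasoconstrictor peptide gene EDN1 at 0.59 ± 0.06 and the transcription factor ATF3 at 0.56 ± 0.06. The largest falls included the chemokine receptor ACKR3 at -1.27 ± 0.15, the cytokine IL11 at -1.09 ± 0.09, the proteoglycan SPOCK1 at -1.09 ± 0.07 and the fibrillar collagen chains COL11A1 and COL5A1 both at -0.81 ± 0.08.

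**Figure D1:**
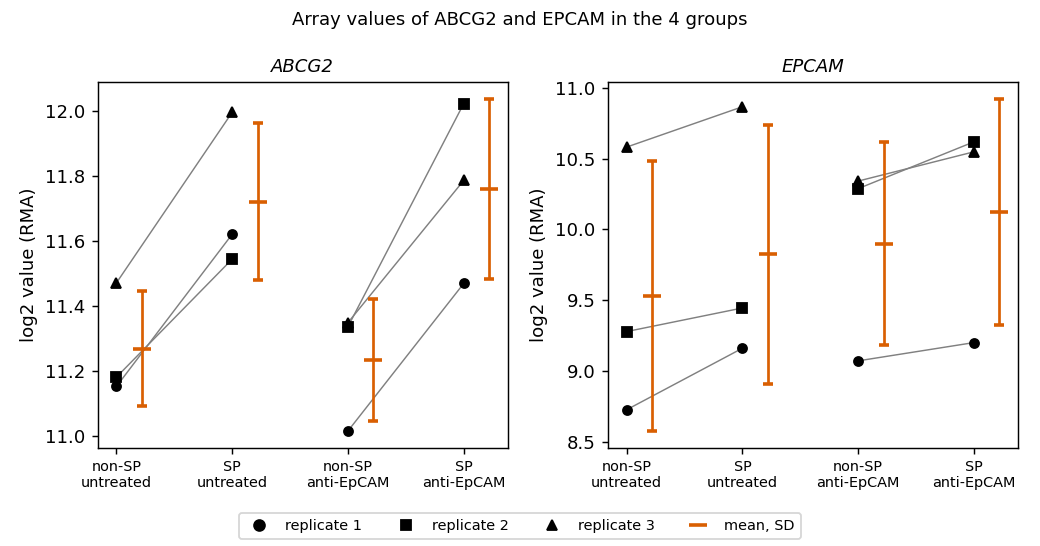
Array values (RMA log2) of ABCG2 (left) and EPCAM (right) in the 4 groups. Each black symbol is 1 array, its shape gives the replicate number, grey lines join the SP and non-SP arrays of a sorted pair, and orange bars show the mean and SD of 3 arrays. Both genes were higher in the SP array of all 6 pairs, while the SD of EPCAM among untreated non-SP arrays was 0.95.

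The remaining members of the 10 largest rises were TIPARP (0.65), an ADP-ribosyltransferase induced by the aryl hydrocarbon receptor, HS3ST3B1 (0.58), a heparan sulfate sulfotransferase, CEMIP (0.57), which takes part in hyaluronan breakdown, KLHL15 (0.56) and FRMD4B (0.55). Among the 10 largest falls were also the long noncoding RNAs CARD8-AS1 (-0.90) and RNF139-DT (-0.84), BCL2A1 (-0.86), an anti-apoptotic member of the BCL2 family, the basement membrane collagen chain COL4A3 (-0.79) and the neurofilament gene NEFL (-0.77). In all, 362 genes passed over the 6 pairs, of which 150 rose and 212 fell, and 344 of them had the same sign in all 6 pairs. The planned limma fit of 12 independent arrays called 0 genes, with 220 at an unadjusted p under 0.05 and a smallest adjusted p = 0.157, for IL11. For ABCG2 and EPCAM that fit gave the same estimates with SE of 0.13 and 0.43. The count over pairs fell to 145 without untreated pair 1, 184 without untreated pair 2, 90 without untreated pair 3, 72 without anti-EpCAM pair 2 and 218 without anti-EpCAM pair 3. It was 27 without anti-EpCAM pairs 1 and 3, whose arrays differed most in an RNA integrity control. Of 52 named passing genes, 24 passed without any 1 of the pairs, among them ABCG2 (highest adjusted p = 0.0223), NR4A3, RND1, CXCL2, EDN1, ATF3, ACKR3, IL11, SPOCK1, COL11A1 and COL5A1. Without anti-EpCAM pairs 1 and 3 together, 7 of the 52 passed: ABCG2 (adjusted p = 0.0394), IL11, SPOCK1, CARD8-AS1, RNF139-DT, COL11A1 and COL4A3. NR4A3 (0.0837), RND1 (0.0609), CXCL2 (0.0543), EDN1 (0.0535), ATF3 (0.0672), ACKR3 (0.0604) and COL5A1 (0.0602) then lost the call, by adjusted p. Log2 changes of the 45 genes that lost it were 0.714 to 1.41 times those over 6 pairs, as in NR4A3 (0.67 ± 0.13) and ACKR3 (-1.28 ± 0.18). Each SE was larger and 2 residual degrees of freedom were left of 4. TIPARP, CEMIP, KLHL15, COL4A3 and NEFL lost the call without at least 1 of the pairs, with highest adjusted p values of 0.0551, 0.0975, 0.0660, 0.0569 and 0.0932. When 1 pair was left out, EPCAM passed only without anti-EpCAM pair 1 (adjusted p = 0.0469) and reached adjusted p = 0.166 without untreated pair 3. EPCAM had adjusted p = 0.0639 without the filter on dim probe sets and adjusted p = 0.0583 with the GAPDH control ratio as a covariate.

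**Figure D2:**
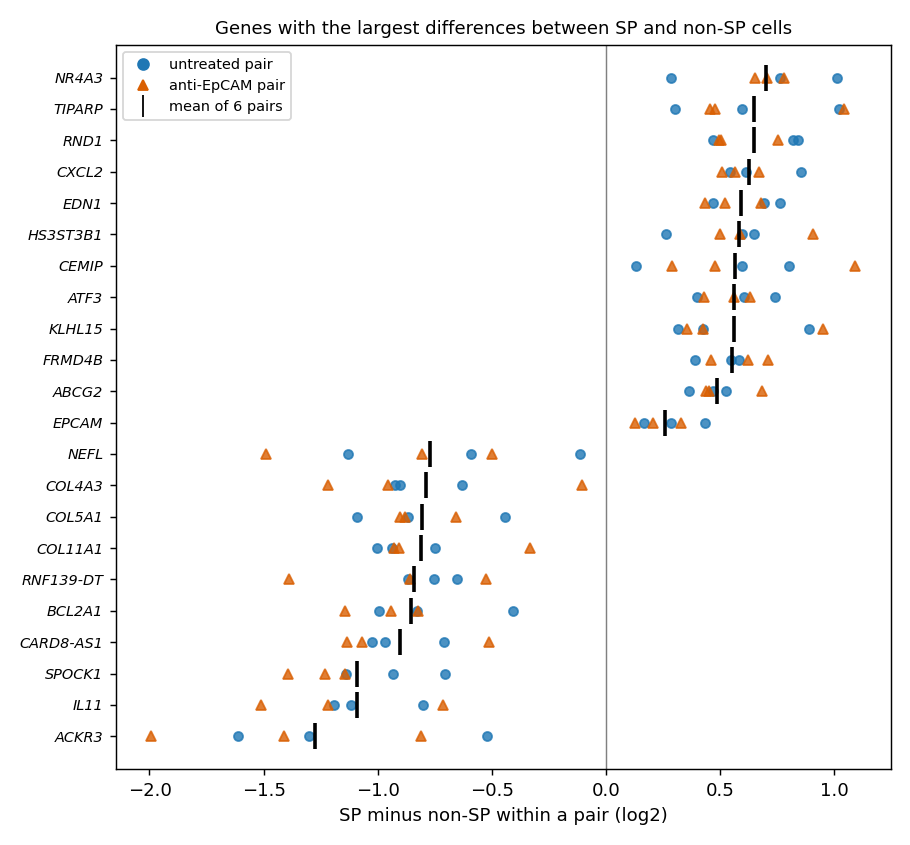
Differences between the SP and the non-SP array (log2, horizontal axis) of each sorted pair for the 10 largest rises, ABCG2, EPCAM and the 10 largest falls. Blue circles are untreated pairs, orange triangles anti-EpCAM pairs and black bars the mean of 6 pairs. ACKR3 spanned -1.99 to -0.52 and NR4A3 spanned 0.28 to 1.01 over the pairs.

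Of the list members named in what follows, EGR1, FOS, COL4A1, COL1A1, PMEPA1, ZMAT3, TP53INP1 and NPC2 also passed without any 1 of the pairs. The other passing members named by the rule did not, with highest adjusted p values from 0.0555 for CXCL3 to 0.205 for PPM1D. With the GAPDH control ratio, a measure of RNA quality, as a covariate, LIN28B (0.0650), UBE2C (0.0685), PPM1D (0.0650), SLC2A3 (0.0557), PDK4 (0.0661) and FGA (0.0638) lost the call, by adjusted p. With EPCAM, their log2 changes were 0.917 to 1.02 times those without the covariate. Without the filter UBE2C (0.0526), IRF1 (0.0527), PPM1D (0.0616), FGA (0.0552) and PHLDA1 (0.0616) lost it.

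Of 19 measured immediate-early and dissociation stress genes, which respond within minutes to growth factors or cell handling, 7 rose in SP cells and 0 fell, and 12 rose when adjusted over the list alone. EGR1 (0.53), FOS (0.45) and MYC (0.40) were among them with ATF3, and 1 of the other EGR1 probe sets had the opposite sign. The list mean was higher in SP cells in all 6 pairs, by 0.22 ± 0.067 (SD, n = 6 pairs; exact sign-flip p = 0.03125, the smallest that 6 pairs allow). That p was reached by 7 of the 38 lists and did not pass when adjusted over them (adjusted p = 0.170). The camera test gave adjusted p = 9.98e-09 for the list, and adjusted p = 0.51 with an estimated correlation. Of 20 measured NF-kB and inflammatory targets, 5 rose and 1 fell, against 6 and 1 when adjusted over the list alone. The chemokines CXCL1 (0.41) and CXCL3 (0.39) and the prostaglandin synthase PTGS2 (0.35) rose with CXCL2, while the monocyte chemokine CCL2, named after its value was seen, fell by 0.51 on the log2 scale. That list had adjusted p = 0.00715 by camera and adjusted p = 0.51 with an estimated correlation.

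Of 15 measured mesenchymal markers, 4 fell in SP cells and 0 rose, against 4 and 1 when adjusted over the list alone. These were COL5A1, the basement membrane collagen COL4A1 (-0.60), N-cadherin CDH2 (-0.41) and the matrix protein TGFBI (-0.33). The list mean was lower in SP cells in all 6 pairs, by -0.16 ± 0.060 (SD, n = 6 pairs; exact sign-flip p = 0.03125, adjusted p = 0.170). Camera gave adjusted p = 0.00413, and adjusted p = 0.51 with an estimated correlation. Among 6 measured fibroblast markers COL1A1 (-0.57) and the smooth muscle actin ACTA2 (-0.29) fell and the other members did not pass, with adjusted p = 0.082 for the list. Of 14 measured TGF-beta targets, 4 fell and 1 rose, against 5 and 3 when adjusted over the list alone. PMEPA1, an inhibitor of TGF-beta signalling, fell by 0.37 on the log2 scale, and SKIL, a repressor of SMAD proteins, rose by 0.35, though 1 of its 2 other probe sets had the opposite sign. The mean of this list was -0.076 and its median 0.037, with adjusted p = 0.424. Of 16 measured epithelial markers, EPCAM rose and the other members did not pass, also when adjusted over the list alone, with adjusted p = 0.547 for the list. Of 16 measured EpCAM partners and signalling genes EPCAM alone passed, against 1 rise and 1 fall when adjusted over the list alone. That list had a mean of -0.014, a median of 0.032 and adjusted p = 0.88.

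Of 27 measured G1/S and DNA replication genes, 26 had a higher estimate in SP cells, but 0 passed in limma over all genes and 5 passed when adjusted over the list alone. At an unadjusted p under 0.05 limma counted 2377 genes over the whole array. The replication licensing factor CDC6 had 0.33 ± 0.09 (adjusted p = 0.0963) and the helicase subunit MCM5 had 0.20 ± 0.06 (adjusted p = 0.108). The list mean was 0.12 ± 0.11 (SD, n = 6 pairs), above 0 in 5 of the pairs, with adjusted p = 1.08e-05 by camera and adjusted p = 0.51 with an estimated correlation. Of 29 measured G2/M and mitosis genes, only the ubiquitin-conjugating enzyme UBE2C passed, at -0.34, and the list had adjusted p = 0.88. MKI67, a proliferation marker, had an estimate of 0.00064 ± 0.051 (adjusted p = 0.997).

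**Figure D3:**
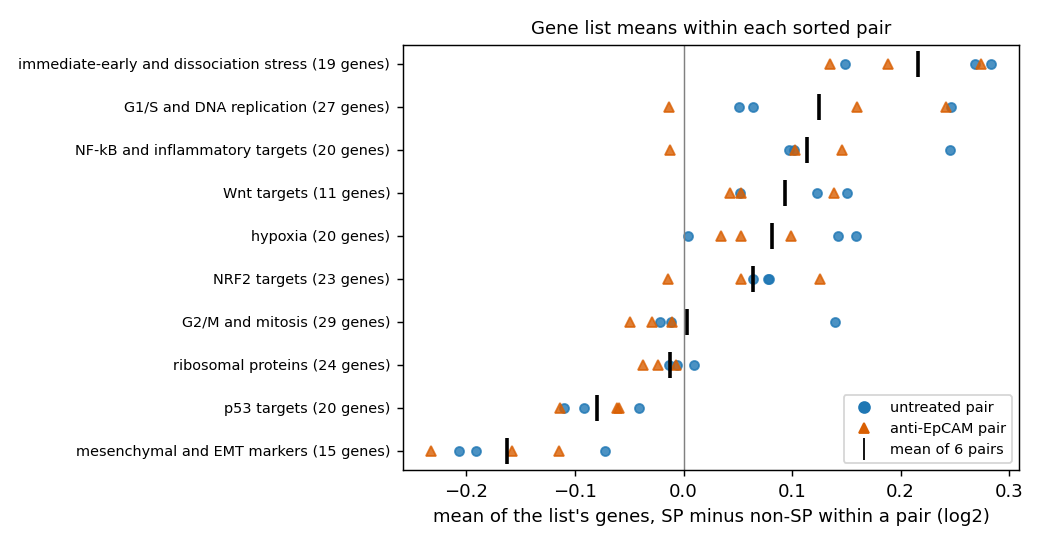
Mean difference between the SP and the non-SP array (log2, horizontal axis) over the genes of a list, for each sorted pair. Lists are the 8 that passed camera over the pairs, and, for comparison, G2/M and mitosis and the ribosomal proteins. Blue circles are untreated pairs, orange triangles anti-EpCAM pairs and black bars the mean of 6 pairs. The immediate-early list lay between 0.13 and 0.28 in all 6 pairs, and the mesenchymal list between -0.23 and -0.072.

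The other 4 lists that passed camera over the pairs had adjusted p = 0.51 with an estimated correlation as well. Of 20 measured p53 targets, ZMAT3 (-0.61) and TP53INP1 (-0.40) fell and the phosphatase PPM1D (0.29) rose, against 4 and 1 when adjusted over the list alone (adjusted p = 0.0482). Of 20 hypoxia genes, DDIT4, an inhibitor of mTOR signalling, rose by 0.29, and 7 rose and 1 fell when adjusted over the list alone (adjusted p = 0.0301). Of 23 NRF2 targets, GCLC, the catalytic subunit of the enzyme that starts glutathione synthesis, rose by 0.32, and 2 rose when adjusted over the list alone (adjusted p = 0.0482). Of 11 Wnt targets, MYC rose, and 2 rose when adjusted over the list alone (adjusted p = 0.0482). Without pairs 8 lists passed camera as well, among them adhesion and integrins (adjusted p = 0.0336), which had adjusted p = 0.0677 over the pairs. With an estimated correlation 0 lists passed without pairs, with a smallest adjusted p = 0.373, and adjusted p = 0.987 for adhesion and integrins. By fry, which asks whether the genes of a list move on balance in a single direction, the immediate-early list passed over the pairs (adjusted p = 0.049), and 0 lists passed without pairs, where 1 list had an unadjusted p under 0.05.

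Of 13 measured ABC transporters, ABCG2 rose and the other members did not pass, against 1 rise and 1 fall when adjusted over the list alone. The drug efflux pump ABCC1 had -0.051 ± 0.060 (adjusted p = 0.731), and ABCB1 was below the filter. This list had adjusted p = 0.507. Of 17 measured stem cell markers, the telomerase subunit TERT (0.30) and the RNA-binding protein LIN28B (0.33) rose and 0 fell, against 4 and 1 when adjusted over the list alone. The list had a mean of 0.027, a median of -0.024 and adjusted p = 0.88. SOX2 had 0.25 ± 0.07 (adjusted p = 0.119), CD44 had -0.12 ± 0.05 (adjusted p = 0.306) and ALDH1A1 had 0.020 ± 0.058 (adjusted p = 0.906), none of which passed. PROM1 and NANOG were below the filter, and POU5F1 was not analysed here because its probe set is shared with other genes. CCND1 (0.080, adjusted p = 0.574) and CDKN1A (-0.14, adjusted p = 0.377) did not pass. For ABCC1, CD44, CCND1 and MKI67 at least 1 other probe set had the opposite sign.

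In untreated cells alone the same question was asked over 3 pairs. RND1 (0.71 ± 0.09), CXCL2 (0.67 ± 0.08), EDN1 (0.64 ± 0.08) and ATF3 (0.58 ± 0.08) rose in SP cells. IL11 (-1.04 ± 0.13), SPOCK1 (-0.93 ± 0.09), CARD8-AS1 (-0.90 ± 0.12), COL11A1 (-0.90 ± 0.11), the cytoskeletal regulator DPYSL3 (-0.80 ± 0.09), COL5A1 (-0.80 ± 0.11), the arrestin-domain gene ARRDC4 (-0.77 ± 0.10), BCL2A1 (-0.74 ± 0.11), the decoy death receptor TNFRSF10D (-0.69 ± 0.09) and LYPD1 (-0.55 ± 0.08) fell. These 4 rises and 10 falls are all 14 genes that passed, and each had the same sign in the 3 pairs (errors are SE, n = 3 pairs). ABCG2 had 0.45 ± 0.08 (adjusted p = 0.0869) and EPCAM had 0.29 ± 0.08 (adjusted p = 0.266), and neither passed. The limma fit of independent arrays called 0 genes, with 56 at an unadjusted p under 0.05. The count over pairs fell to 4 without untreated pair 1, and to 0 without untreated pair 2, without untreated pair 3 or without anti-EpCAM pair 2, which shares the estimate of the spread. By camera 6 lists passed with or without pairs, led by the immediate-early list (adjusted p = 1.29e-08 over the pairs), and 0 passed with an estimated correlation (adjusted p = 0.491 for that list).

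In antibody-treated cells 36 genes passed over 3 pairs, 8 of them higher and 28 lower in SP cells, each with the same sign in the 3 pairs. The rises were NR4A3 (0.71 ± 0.12), HS3ST3B1 (0.66 ± 0.10), FRMD4B (0.60 ± 0.08), RND1 (0.58 ± 0.09), CXCL2 (0.58 ± 0.08), EDN1 (0.55 ± 0.08), ATF3 (0.54 ± 0.08) and ABCG2 (0.53 ± 0.08, adjusted p = 0.0469). The 10 largest falls were ACKR3 (-1.40 ± 0.22), SPOCK1 (-1.26 ± 0.09), IL11 (-1.15 ± 0.13), BCL2A1 (-0.97 ± 0.11), RNF139-DT (-0.92 ± 0.13), CARD8-AS1 (-0.90 ± 0.12), the pseudogene FRG1BP (-0.86 ± 0.12), the vitamin B12 carrier TCN1 (-0.82 ± 0.14), COL5A1 (-0.81 ± 0.11) and TNFRSF10D (-0.78 ± 0.09). EPCAM had 0.22 ± 0.08 (adjusted p = 0.365). The limma fit of independent arrays called 0 genes, with 58 at an unadjusted p under 0.05. The count over pairs fell to 5 without anti-EpCAM pair 1, 0 without anti-EpCAM pair 2 and 9 without anti-EpCAM pair 3, and to 0 without pairs 1 and 3 together. By camera 3 lists passed over the pairs and 5 without pairs. The immediate-early list led over the pairs (adjusted p = 9.87e-08), and 0 passed with an estimated correlation (adjusted p = 0.662 for that list).

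Of the genes called in untreated and in treated pairs, 13 were shared, against 0.0344 expected for independent lists, and all 13 had the same direction. Both contrasts use the same estimate of each gene's spread, which favours overlap. Treated and untreated pairs of the same number may also not be independent, so the value expected for independent lists is no fair comparison. Across genes, which are not independent replicates, the fraction effects in untreated and treated pairs correlated with Pearson r of 0.63 and Spearman rho of 0.54, and 67.8% of genes had the same sign. Whether the fraction effect differed between treated and untreated cells was tested by the interaction. It called 0 genes in limma, with 0 at an unadjusted p under 0.05 without pairs and 249 over pairs. It called 0 lists by camera or fry, with 3 lists by camera and 0 by fry at an unadjusted p under 0.05 without pairs. The interaction estimate was 0.074 ± 0.11 for ABCG2 and -0.073 ± 0.11 for EPCAM (SE over pairs, adjusted p = 1.00 for both). The smallest p over pairs belonged to CHRDL2 (-0.69 ± 0.14), an antagonist of BMP signalling, and the histone gene H2BC4 (0.40 ± 0.10), neither of which passed (adjusted p = 1.00).

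The next question was what the EpCAM antibody changed. EPCAM itself did not pass, with 0.37 ± 0.60 in non-SP cells and 0.30 ± 0.60 in SP cells (SE, 3 arrays against 3, adjusted p = 1.00 for both), and 0.33 ± 0.43 over both fractions (adjusted p = 0.984). Its mean was 9.53 ± 0.95 (SD, n = 3) in untreated and 9.90 ± 0.72 in treated non-SP cells, and 9.83 ± 0.91 and 10.12 ± 0.80 in SP cells. These differences were smaller than the spread between replicates, and the estimate in non-SP cells was -0.030 without untreated non-SP replicate 1, and that in SP cells -0.033 without untreated SP replicate 1. ABCG2 had 0.0021 ± 0.13 (adjusted p = 0.998). The genes of smallest p over both fractions were UNC5A (0.84 ± 0.14), a netrin receptor, GTSF1L (0.79 ± 0.15), the glutamate transporter SLC1A2 (0.59 ± 0.13), GPR21 (0.56 ± 0.12) and ZNF594-DT (0.54 ± 0.10) above 0, and the noncoding RNA JPX (-0.78 ± 0.21), ZNF566 (-0.69 ± 0.19), LOC105379426 (-0.51 ± 0.11), MAGOHB (-0.37 ± 0.10) and UNC13D (-0.34 ± 0.08) below 0. None of these passed (adjusted p = 0.984 for each), and for UNC13D and MAGOHB another probe set had the opposite sign.

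For the antibody limma called 0 genes in non-SP cells, 0 in SP cells and 0 over both fractions, with 93, 78 and 350 at an unadjusted p under 0.05, where 732 are expected by chance. In simulated data the fit over both fractions called 81% of log2 changes of 1, with 302 false calls. A fit of pair means called 36% of them. The 0 calls therefore do not show that the antibody changed no gene. In non-SP cells the smallest p belonged to LOC105379426 (-0.72 ± 0.15) and ZNF594-DT (0.68 ± 0.15), and in SP cells to UNC5A (0.83 ± 0.20) and GPR21 (0.64 ± 0.17). The 38 gene lists gave 0 calls by camera and by fry in each of these contrasts, and camera had 2, 1 and 3 lists at an unadjusted p under 0.05. Over both fractions the G1/S list had a mean of 0.019 while camera, which compares it with all genes, placed it below them (adjusted p = 0.414). The arrays appear to have been normalised in the 6 sorted pairs. Treated and untreated arrays were then normalised apart, and so were the replicates of each treatment. The median of all genes was shifted by 0.10 in non-SP and 0.077 in SP cells. After quantile normalization over the 12 arrays those shifts were 0.022 and 0.00059, and 1 gene passed over both fractions. Array weights gave 8344 calls in non-SP cells and 8320 over both fractions, and a block on the replicate number gave 81 over both fractions. The antibody effects in non-SP and SP arrays correlated across genes with r of 0.74 and rho of 0.71, but 6 of the 10 groupings of the 6 pairs into sets of 3 gave a value at least as large.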

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

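The tests of the immediate-early pattern, the test of the share of cycling cells, the groupings for the correlations of effects, and those for the lists over 3 pairs and for the paired interaction of lists were chosen after the results were seen, as was the use of sorted pairs. The other tests of explanations were written before their results were seen, apart from the values of single pairs set beside the ACTB control ratio. For fibroblasts the rule written then asked only whether the mean level of 4 genes lay below the filter. That level, 5.20 against 5.39, met the rule, which would have argued against them. A stricter rule is used below, because genes so near the filter decide little.

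Immediate-early and dissociation stress genes were higher in SP cells by a mean of 0.22 in all 6 pairs. An RNA integrity difference within pairs is argued against. The ACTB control ratio differed by 1.86 in anti-EpCAM pair 1 and by -2.09 in pair 3. The list rose in both, by 0.27 and 0.19. At a difference of 0 in that ratio the mean shift was 0.22 (95% interval 0.14 to 0.30). Those differences nearly cancel, which keeps this value near the plain mean and makes it weak evidence by itself. A scale offset left in the deposited values is argued against as well, since the largest absolute median difference of all genes within a pair was 0.063. The arrays of a pair look normalised together, which keeps that median near 0. An offset before normalization therefore cannot be judged from it. Dye kept by non-SP cells may lower short-lived transcripts there, and genes named ZNF, many of them short-lived, lay above the all-gene median in 6 of 6 pairs. That class was picked after its rise was seen and decides nothing, and dye content defines the sort, so dye cannot be told apart from a biological difference between the fractions, which was not tested.

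Mesenchymal markers, several of them collagens, were lower in SP cells by a list mean of -0.16, below 0 in all 6 pairs. An RNA integrity difference is argued against. The list fell in anti-EpCAM pair 1 (-0.11) and in pair 3 (-0.23), though their ACTB control ratios differed in opposite directions (1.86 and -2.09). At a difference of 0 in that ratio the mean shift was -0.16 (95% interval -0.22 to -0.098). Those differences nearly cancel, which keeps this value near the plain mean and makes it weak evidence by itself. Fibroblasts among the non-SP cells cannot be told apart from a difference of matrix gene expression between the fractions, because the 4 genes named in advance to test them, COL1A2, COL3A1, DCN and LUM, lay near the filter of 5.39 (mean level 5.20 in non-SP arrays, 3.73 for LUM to 6.17 for DCN). Their mean change of -0.070 (95% interval -0.25 to 0.11) did not reach the -0.81 of COL5A1 expected of fibroblasts, with COL1A2 at 0.13, DCN at -0.052, LUM at 0.011 and COL3A1, like LUM below the filter, at -0.37. On the other side COL1A1 (-0.57) and ACTA2 (-0.29) fell. The mean of the 6 of 11 fibroblast markers that A549 arrays held above the filter was -0.15, below 0 in 5 of 6 pairs. That mean includes COL1A1 and ACTA2, as well as COL1A2 and DCN, so it is not separate evidence.

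G1/S genes were higher in SP cells by a mean of 0.12 while the G2/M list had 0.0028. At a difference of 0 in the ACTB control ratio the G1/S shift was 0.12 (95% interval 0.023 to 0.21). This cannot decide on RNA integrity. The differences of 1.86 and -2.09 in anti-EpCAM pairs 1 and 3 nearly cancel, which keeps that value near the plain mean. The G1/S mean was -0.014 in pair 1 and 0.24 in pair 3, lower where the ratio was higher. The other pairs, with ratio differences of -0.36 to 0.27, had G1/S means of 0.051 to 0.25. A larger share of cycling cells in SP could raise both lists and cannot be told apart from a shift toward G1/S, since the G2/M interval of -0.069 to 0.074 includes 0.062, which is 0.5 of the G1/S shift. That reach rests on untreated pair 1, where the G2/M mean was 0.14; it was below 0 in the 5 other pairs, with a mean of -0.024 without that pair. The difference between the lists was 0.12 and above 0 in 5 of 6 pairs (exact sign-flip p = 0.125).

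A signal appeared in data the comparisons do not use. Among kept probe sets without a single gene name, 67 of 5675 passed between SP and non-SP over the 6 pairs (14 higher, 53 lower), a share of 1.18% against 0.528% of named probe sets. The 3-prime to 5-prime ratio of the ACTB control probe sets, which rises as RNA degrades, differed within pairs by 1.86 (SP minus non-SP) in anti-EpCAM pair 1 and by -2.09 in anti-EpCAM pair 3, against -0.36 to -0.25 in the untreated pairs.

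Other groupings of the arrays were counted for the gene counts, the list counts by camera and the correlations of effects. For the paired count of 362 genes, 1 of 32 sign patterns of the 6 pairs gave as many, the real one, and the highest other gave 1. Chance can be excluded at a share of 0.05 only if the 6 pairs are independent, which was not tested. Were pairs of the same number 1 experiment, only 4 sign patterns would be left, too few for such a share. On the same condition chance can be excluded for the correlation of fraction effects (1 of 32, 0.63 against a highest other of 0.48). For the 8 paired lists it can be excluded on that condition by a margin of 1 list (1 of 32, highest other 7), and 0 of those lists passed with an estimated correlation (smallest adjusted p = 0.51). For the 8 lists without pairs, 3 of 100 drawn splits gave as many with a highest other of 8, but these splits break the correlated pairs and so decide nothing. With 3 pairs there are only 4 sign patterns, too few for a share under 0.05: untreated pairs gave 14 genes with a highest other of 0, and treated pairs 36 with a highest other of 11, while the lists gave 6 and 3, each with a highest other of 2. The 10 splits of 3 arrays against 3 are too few as well. There the lists gave 6 in untreated cells (2 of 10 splits, highest other 6) and 5 in treated cells (3 of 10, highest other 8), and the correlation of antibody effects, 0.74, was met by 6 of 10, with a highest other of 0.91.

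A count of 0 is met by every split, so the splits say nothing on chance for the results at 0. For the single contrasts and the interaction these were 10 of 10 splits, with a highest other of 0 genes, or 6 for the paired interaction, and 6, 5 and 3 lists for the antibody in non-SP, in SP and the interaction, or 4 lists for the paired interaction. For the averaged contrasts they were 100 of 100 drawn splits, with a highest other of 4242 genes for the fraction, 4141 genes for the antibody and 7 lists for the antibody. Splits that call so many genes point to a structure of the samples. Among the 10 splits that keep sorted pairs whole, the highest other called 10298 genes: it set untreated pairs 1 and 2 and anti-EpCAM pair 1, with array medians of 5.58 to 5.84, against untreated pair 3 and anti-EpCAM pairs 2 and 3, with 6.14 to 6.24. With these sets of pairs as a block the antibody contrast called 2 genes over the 12 arrays.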

How the results depend on the processing

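Added after seeing the data were the sorted pairs with all their alternatives, the random block on pairs, gene-by-gene array weights and the block on array level; the other settings were planned. No setting changed the interaction counts, and none changed the antibody count in SP cells. Arrays have no read depth, no background level was measured, and genes below the filter of 5.39 were compared only in the setting without it, apart from COL3A1 and LUM, used to weigh fibroblasts. Unless a reason is given the cause was not tested.

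Without pairs each gene count was 0. For SP against non-SP in untreated cells it became 32 with array weights, 1 with gene-by-gene weights, 16 with the pair as a random block and 14 over sorted pairs. In treated cells it became 1 with array weights, 22 with the random pair block and 36 over sorted pairs. Averaged, it became 10 with a fixed and 3 with a random block on the replicate number, 21 with array weights, 4 with gene-by-gene weights, 7 with the array level block, 393 with the random pair block (272 shared with the 362) and 362 over sorted pairs. For the antibody in non-SP cells it became 8344 with array weights and 5 with gene-by-gene weights. For the antibody averaged it became 81 with a fixed and 20 with a random block on the replicate number, 1 after quantile normalization, 8320 with array weights, 5512 with gene-by-gene weights, 2 with these after quantile normalization and 2 with the array level block. Leaving out each array gave 0 to 0 genes in every contrast. The fit of array weights stopped before converging and put a weight of 74.3 on untreated non-SP replicate 2, against 0.169 to 3.96 on the others; the median antibody effect of all genes was then 0.256 instead of 0.0910. With pair means, 3 pairs against 3, the averaged antibody count was 0.

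Over sorted pairs the untreated count of 14 became 0 without the block, 0 with all probe sets as units, 61 with trend and robust moderation, 113 with array weights, 0 at an adjusted p under 0.01 and 9 with the GAPDH ratio as covariate; leaving out each pair gave 0 to 16. The treated count of 36 became 0 without the block, 14 without the filter, 0 with all probe sets, 13 with the mean of a gene's probe sets, 13 without probe sets named _x_at, 90 with trend and robust moderation, 5 with array weights, 1 at an adjusted p under 0.01, 9 with the GAPDH ratio and 0 without anti-EpCAM pairs 1 and 3; leaving out each pair gave 0 to 32. The averaged count of 362 became 0 without the block, 210 with all probe sets (51 higher, 159 lower), 33 with a fold of at least 1.5, 59 at an adjusted p under 0.01 and 27 without anti-EpCAM pairs 1 and 3 (18 shared); leaving out each pair gave 72 (without anti-EpCAM pair 2) to 430 (without anti-EpCAM pair 1). Stricter thresholds lower counts by construction, and without anti-EpCAM pairs 1 and 3 the remaining treated pair is assumed to vary like the untreated ones. After quantile normalization 351 genes passed, 337 of them shared, and with the ACTB ratio as covariate 429, 351 shared. Of 1540 alternative values of the 84 named gene results that passed over pairs, 1036 stayed past the threshold, 504 kept their direction and lost it, and 0 reversed. The largest rises and falls were picked for the same sign in every pair, so leaving out pairs could not reverse them. Dropping the block keeps every estimate, so it could reverse none. The absence of reversals is therefore in part fixed by the choice of genes.

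List counts by camera without pairs were 6 in untreated, 5 in treated and 8 in averaged fraction contrasts. They became 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry, and over sorted pairs 0, 0 and 0 with an estimated correlation and 0, 0 and 1 with fry. The treated count was 3 with the block on the replicate number and 3 over sorted pairs. The correlation of fraction effects, 0.63, was 0.71 at the 60th percentile filter and 0.35 (without untreated non-SP replicate 3) to 0.55 when 1 array was left out. That of antibody effects, 0.74, was 0.36 (without anti-EpCAM SP replicate 3) to 0.71. Leaving out 1 array of a pair breaks the pairing.

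Estimates that reversed had not passed in the fit that reversed them. EPCAM averaged over treatment passed over sorted pairs, where leaving out each pair gave 0.22 to 0.29; the EPCAM values that follow are from the fit without pairs. Leaving out each array gave EPCAM -0.23 to 0.82 for the fraction in untreated, -0.19 to 0.68 in treated and -0.0020 to 0.52 in averaged contrasts, -0.030 to 0.90 for the antibody in non-SP and -0.033 to 0.82 in SP cells, and -0.60 to 0.45 for the interaction, which was 0.27 with the GAPDH ratio. For the averaged antibody contrast the same ranges were -0.064 to 0.074 for ABCG2, -0.054 to 0.095 for MYC and -0.099 to 0.014 for MKI67. There quantile normalization gave -0.058 for ABCG2 and -0.019 for MYC, and the GAPDH ratio -0.0019 for ABCG2. Median centring, which removes the all-gene shift, gave ABCG2 -0.13, ABCC1 -0.027, CD44 -0.045, ALDH1A1 -0.062, MYC -0.096, CCND1 -0.015 and CDKN1A -0.026, and the mean of a gene's probe sets gave CCND1 -0.21 and MKI67 0.090. Over sorted pairs the mean of a gene's probe sets gave TNFRSF19 -0.23 (from 0.16), XIAP -0.037 (from 0.14), RRP12 -0.00012 (from 0.20), CPT1A 0.086 (from -0.076) and CCND1 -0.10 (from 0.080). MKI67 was -0.012 after quantile normalization, -0.0019 with the GAPDH ratio and -0.012 without anti-EpCAM pairs 1 and 3. Leaving out each pair gave PDGFRB -0.11 to 0.020, ALDH1A1 -0.016 to 0.071, MKI67 -0.014 to 0.024 and the mean of the G2/M list -0.024 to 0.013, and that mean was -0.011 after quantile normalization.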

Other observations

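The gene classes in this paragraph were picked after some of their members were seen to move over the same pairs, so their counts describe these data and are no test. Among 31 measured collagen chain genes, 7 fell in SP cells over the 6 pairs and 0 rose. Besides COL11A1, COL5A1, COL4A3, COL4A1 and COL1A1 these were COL4A2 (-0.65, adjusted p = 0.00378) and COL4A5 (-0.39, adjusted p = 0.0374). Not all chains moved: COL5A2, the chain with the highest mean level of 12.09, had 0.053 (adjusted p = 0.731). Among 353 genes named ZNF, 21 rose and 4 fell.

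Other genes that passed over the 6 pairs belonged to lists that did not pass. Among growth factor receptors and EGFR ligands, the phosphatase DUSP6 (0.36), the ligand EREG (0.38) and PHLDA1 (0.34, 1 of its 5 other probe sets of opposite sign) rose in SP cells and 0 of 19 fell, against 3 and 1 when adjusted over the list alone; the list mean was 0.038, its median -0.014 and its adjusted p = 0.686. In lysosome and autophagy the cholesterol transporter NPC2 fell by 0.41 and WIPI1 fell by 0.30 on the log2 scale, among 19 members, the same count as when adjusted over the list alone (adjusted p = 0.704, mean -0.026, median 0.0067). The glucose transporter SLC2A3 (0.40), the pyruvate dehydrogenase kinase PDK4 (0.33) and the fibrinogen chain FGA (0.30) rose, and IRF1 (-0.26), an interferon regulatory factor, fell.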
